A study of Rattus norvegicus and Mus musculus with 25 samples.

How the data were processed

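The samples are 16 rat libraries in 2 tables (12 and 4 libraries) and 9 mouse libraries in 1 table. Total RNA was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. Rat cells were digested from ventricles and pre-plated to remove faster-attaching cells, per the labels' protocols; how the mouse cells were prepared is not given in the sources used here. The submitters' processing notes list HISAT2 2.1.0, StringTie 1.3.4 and edgeR 3.20.9 and the builds rn6 and mm10, with no roles or order. The deposited values are CPM, made by the authors: every column sums to 1000000, so no composition factor is left in them. The annotation release is not given in the sources used here.

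Columns were matched to samples by name for 23 libraries. The other 2, named Blank and numbered 1 and 2, match no label by name and were assigned to the Control group by elimination. Their numbers were not taken as the replicate numbers of the labels. Row names that occurred more than once (4 rows per table, date-like names made by a spreadsheet) were left out of the tests.

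Depth was examined from the spacing of the values. In each library values are whole multiples of a step, taken as the most common value divided by the smallest whole number that made over 95% of values whole within 0.05 steps. That number was 4 in each library. It made 100% of mouse values and 99.12% to 99.25% of rat values whole, while division by 2 made at most 53.31% whole. The rest of the rat values lie at fractions of a step, so no count test was run on rat. Steps sum to 66088372 to 78370879 in mouse, 77530465 to 97773386 in the 12-library table and 87076477 to 96068041 in the 4-library table. A step need not be a read: the most common value was 4 steps, and 31.5% to 35.8% of low values were multiples of 4, where 25% would be expected with no preference. A fragment could stand for about 4 steps, so the number of fragments is not known and no counting interval is given.

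Because the tables hold CPM, a count test could not be the main test. The fallback fixed before the data were examined was used: limma 3.58.1 (R 4.3.3) with an intensity trend on log2(CPM + 1), genes with CPM of at least 1 in as many libraries as the smallest group (2 in rat, 3 in mouse), 1 mean per group, all groups of a table in a single fit, and Benjamini-Hochberg adjustment with calls at 0.05. Tests were made within a table only. Gene lists (42, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison, and again with an estimated correlation. None of the calls of any comparison held with the estimated correlation, where the smallest adjusted p was 0.29. That correlation is estimated from few libraries, and simulated lists were tested at the preset correlation only. Its power is therefore unknown, and a list that does not pass with it is not shown to be unchanged. Counts adjusted over the list alone are given beside those over all genes.

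Named genes were chosen by a rule: Vldlr, Reln and Thbs1 always; the 8 largest changes per direction among called genes with a mean of at least 5 CPM in a compared group, no overlap of replicates and a gene symbol that is not a predicted or clone identifier; and from each described list the 4 members with the smallest p, of which the text gives some. Counts of 5 or fewer were named in full. Col1a1, Mt-co1, Myh6, Mki67, Isg15, Mapk7, Cdkn1a, Xist, Ddx3y and Kdm5d where given outside this rule were chosen after their values were seen. So were the called genes with predicted identifiers and the lists described out of those tested. Mouse coordinates are from GENCODE M21 on GRCm38 (mm10); rat coordinates were not used here because the reference at hand has another build.

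The fit was tested on simulated data with 67 genes changed 2-fold and 66 changed 4-fold beside 67 with smaller changes. Changed genes had a mean above 5 CPM, noise was independent between genes, and a list of shifted genes was added. So many true changes ease the adjusted threshold, so recovery can be lower in the real data. In the real si-Vldlr fit Ifit3 at 2.2-fold and Timp1 at 2.04-fold were not called (limma adjusted p = 0.102 and 0.0593). In the simulated data the fit recovered 80.6% of genes changed 2-fold for si-Vldlr, 86.6% for Reelin and 88.1% for Vldlr OE (13860 genes each), and 0% for si-Thbs1 (13416 genes). It recovered 11.9% at 2-fold and 74.2% at 4-fold for Myh6-Cre;Vldlr f/f against Vldlr f/f (14922 genes). Beside these changed genes the fit made 4 false calls for si-Vldlr, 8 for Reelin, 5 for Vldlr OE and 0 for si-Thbs1, and in mouse 1 for Myh6-Cre;Vldlr f/f and 3 for Myh6-Cre;Vldlr f/+ against Vldlr f/f and 4 between the Cre genotypes. A list of 40 unshifted genes was also tested by camera in each simulation. Its unadjusted p was 0.00607 between the Cre genotypes, a false call at 0.05, and 0.321 to 0.953 in the other comparisons. In simulated mouse counts for Myh6-Cre;Vldlr f/f against Vldlr f/f, edgeR 4.0.16 made 3 false calls and DESeq2 1.42.0 made 37.

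Replicate numbers were checked as pairs by the correlation of deviations from group means. Myh6-Cre;Vldlr f/+ and Myh6-Cre;Vldlr f/f libraries with the same number correlated at 0.459, 0.439 and 0.333, all above 0.1. Their numbers were taken as pairs on these values alone. Libraries of different number correlated as highly: Vldlr f/f replicate 2 at 0.443 with Myh6-Cre;Vldlr f/f replicate 1 and at 0.412 with Myh6-Cre;Vldlr f/+ replicate 1. The correlations can therefore reflect another structure of the samples, and a pairing is not shown. Neither genotype paired with Vldlr f/f, where same-numbered correlations were as low as -0.545. The fit between the Cre genotypes with equal numbers as a block also called 0 genes. Replicates were distinct: at most 0.216% of tested genes had identical values in any pair of libraries. Alternatives were median-ratio size factors, library size only (which repeats the fit as reported, since the columns already sum to 1000000), no filter, a pseudocount of 0.1, the compared groups alone, a replicate block and leaving out each library, and for mouse DESeq2. Added after seeing the data were edgeR's quasi-likelihood test on the recovered mouse steps and on those divided by 4, sex and the first residual component as covariates, and leaving out genes that switch between 0 and at least 5 CPM. Median-ratio scaling moved the median log2 fold change of all genes from -0.11 to 0.00 for Myh6-Cre;Vldlr f/f against Vldlr f/f.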

Results

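RNA was sequenced from 25 libraries of heart muscle cells in which the very low density lipoprotein receptor gene Vldlr, or a ligand of that receptor, was manipulated. Reelin (gene Reln) and thrombospondin-1 (gene Thbs1) are secreted proteins, and the series title names both as acting through this receptor on cardiomyocyte proliferation. In rat, 16 libraries came from neonatal ventricular cardiomyocytes of 1-day-old animals. They form 8 groups of 2: si-Vldlr and its si-control, Reelin and PBS, Vldlr overexpression (Vldlr OE) and Control, and si-Thbs1 and its si-control. In mouse, 9 libraries came from cardiomyocytes of 1-day-old animals with 3 genotypes of 3 libraries each. Myh6-Cre;Vldlr f/f carries a Cre recombinase under a cardiomyocyte promoter with both Vldlr copies floxed, Myh6-Cre;Vldlr f/+ has a single floxed copy, and Vldlr f/f has no Cre. Levels are given in CPM (values scaled so that each library sums to 1000000) as mean ± SD, and fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The files give CPM and not read numbers, so the depth behind a value is known only in steps of unknown size in reads (66088372 to 97773386 steps per library). Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. In mouse, the Y-linked Ddx3y was 0, 51.4 and 59.89 CPM in Vldlr f/f replicates 1, 2 and 3. It was 0, 28.89 and 0 CPM in those of Myh6-Cre;Vldlr f/f. Libraries of these 2 groups thus did not all come from the same animals, so their spread is not only technical. Myh6-Cre;Vldlr f/+ libraries showed no such difference.

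**Figure D1:**
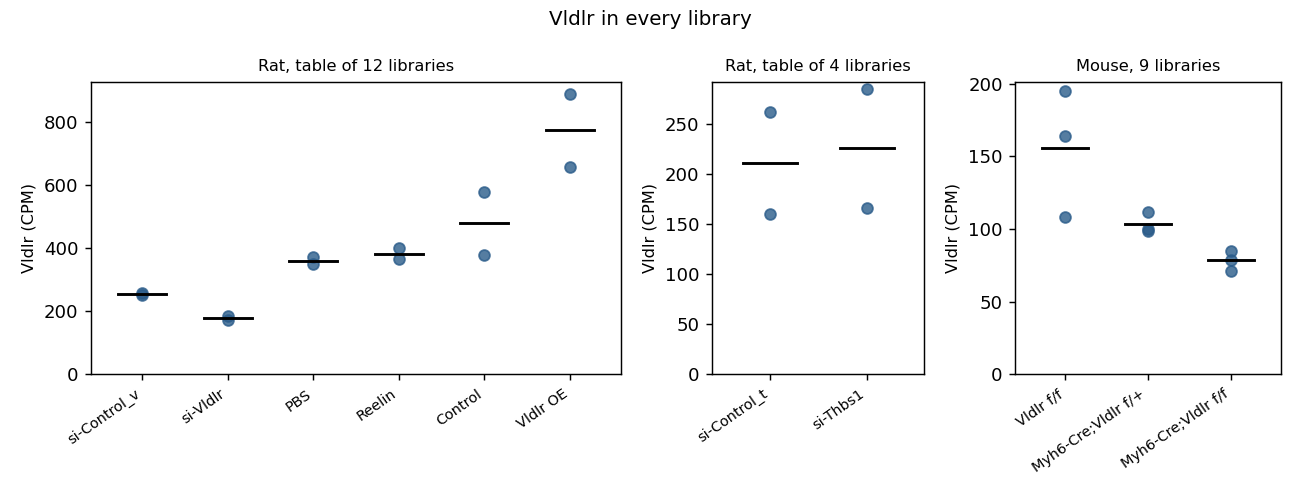
Vldlr level in CPM (vertical axes, starting at 0) in each library by group, in 3 panels for the 3 separately deposited tables, with libraries as points and group means as bars. Vldlr was 171.2 and 183 CPM in the si-Vldlr libraries, 252.5 and 257.1 CPM in their controls, and 71.33 to 85.11 CPM in Myh6-Cre;Vldlr f/f against 108.5 to 194.8 CPM in Vldlr f/f.

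The first comparison asked what loss of the receptor by siRNA (50 nM, 60 h) did to rat cardiomyocytes. Vldlr was 177 ± 8.4 CPM in si-Vldlr and 255 ± 3.3 CPM in the si-control (n = 2 each), a log2 fold change of -0.52 ± 0.18 (SE). Both si-Vldlr libraries lay below both controls, but the change did not pass limma's test (adjusted p = 0.348 over all genes and 0.0521 adjusted over the list alone, the list being Vldlr, Reln and Thbs1). Thbs1 was 1757 ± 151 against 1461 ± 197 CPM, and Reln was 2.3 ± 0.28 against 2.76 ± 1.92 CPM, and neither passed. Of 13860 genes tested, 3 rose and 1 fell at adjusted p under 0.05, while 1630 had an unadjusted p under 0.05, where 693 would be expected by chance. The groups did not overlap in 48.5% of genes, against 33.3% by chance. Olr1, the lectin-like receptor for oxidised low density lipoprotein, rose from 27.75 ± 5.74 to 79.07 ± 1.08 CPM (log2 fold change 1.49 ± 0.14, limma adjusted p = 0.010). Nefm, a neurofilament subunit, rose from 3.44 ± 1.06 to 12.39 ± 0.72 CPM (1.61 ± 0.16, adjusted p = 0.010). The other 2 were Abhd10, listed at 0 and 0.91 CPM in si-Vldlr against 5.03 and 6.54 CPM in the si-control, and LOC100910669, listed at 0 in both controls and at 2.36 and 2.26 CPM in si-Vldlr. Many genes listed at exactly 0 in some libraries also switched on and off between replicates of a group. In the 12 libraries fitted, these 2 did not switch between 0 and at least 5 CPM within a group. In the separate 4-library rat table Abhd10 was 7.37 and 0 CPM in si-Thbs1 replicates 1 and 2. LOC100910669 was 2.398 and 0 CPM there in si-Control_t replicates 1 and 2, so both calls are uncertain. Olr1 was called whichever library was left out, and Nefm was not called without si-Vldlr replicate 2. When the 2 compared groups were fitted alone, 8 genes were called and 0 of these 4 were among them.

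Of 36 gene lists tested, 16 were called for si-Vldlr. Interferon-response genes rose as a group. All 45 tested members had positive fold changes with a median of 1.46-fold (limma camera test with a preset correlation of 0.01, adjusted p = 2.82e-20, and adjusted p = 0.49 with an estimated correlation). No member passed over all genes and 13 passed when adjusted over the list alone. Ifit3, an antiviral effector, was 146 ± 10.4 against 66.1 ± 12.2 CPM, and Ifi44l was 15.1 ± 0.6 against 6.75 ± 1.66 CPM (n = 2 each). The median log2 fold change was 0.55, and 0.35 without si-Control_v replicate 2. Mitosis genes fell as a group: 38 of 39 had negative fold changes, with a median log2 fold change of -0.33 (adjusted p = 2.48e-05, and adjusted p = 0.572 with an estimated correlation), and 0 passed when adjusted over the list alone. Foxm1, a transcription factor of mitotic genes, was 18.2 ± 2.06 against 26.7 ± 2.28 CPM.

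Sarcomere genes fell, with 20 of 24 negative and a median log2 fold change of -0.21 (camera adjusted p = 0.00124, and adjusted p = 0.29 with an estimated correlation). The median was -0.15 without si-Control_v replicate 2 and -0.29 without si-Control_v replicate 1. Myh6 was 1166 and 2685 CPM in si-Control_v replicates 1 and 2 and 942 and 1062 CPM in si-Vldlr. The thick-filament protein gene Mybpc3 was 1434 ± 52.8 against 1895 ± 8.71 CPM and Tnni3, cardiac troponin I, was 363 ± 18.8 against 513 ± 98.4 CPM. All 15 tricarboxylic acid cycle genes were lower (median -0.17, adjusted p = 1.4e-05, and adjusted p = 0.49 with an estimated correlation), and 1 of them, Idh3g, passed when adjusted over the list alone. Fatty acid oxidation genes fell (33 of 35 negative, median -0.19, adjusted p = 6.41e-06, and adjusted p = 0.49 with an estimated correlation), and sterol synthesis genes rose (23 of 25 positive, median 0.22, adjusted p = 1.17e-06, and adjusted p = 0.49 with an estimated correlation). Neither held without si-Control_v replicate 2, in which mitochondrially encoded transcripts took 6.26% of CPM against 4.14% in si-Control_v replicate 1 and 3.8% and 4.17% in si-Vldlr. Without it the medians were -0.06 and 0.05 and the adjusted p was 0.126 and 0.402. Without si-Control_v replicate 1 the medians were -0.31 and 0.40. In the list of TGF-beta targets and matrix genes 30 of 39 were positive (adjusted p = 0.000171, and adjusted p = 0.49 with an estimated correlation). In that list 2 members rose and 1 fell when adjusted over the list alone: Timp1, a metalloproteinase inhibitor, at 202 ± 0.1 against 99.9 ± 24.1 CPM, Lox, a collagen cross-linking enzyme, at 392 ± 25.6 against 246 ± 23.1 CPM, and Eln, elastin, at 411 ± 60.5 against 739 ± 204 CPM. Leaving out 1 library at a time gave 4 to 167 called genes, the highest without si-Control_v replicate 1.

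The second comparison asked what the ligand Reelin did after 48 h. The receptor and ligand genes differed by less than could be called: Vldlr was 382 ± 25.3 CPM with Reelin and 359 ± 15.8 CPM with PBS, a log2 difference of 0.09 with a 95% interval from -0.32 to 0.50. Mitosis genes had a median log2 fold change of 0.11, with 35 of 39 positive, and did not pass (camera adjusted p = 0.421). Of 13860 genes, 1 rose and 1 fell, and 189 had an unadjusted p under 0.05, fewer than the 693 expected by chance. With the Reelin and PBS libraries fitted alone, 391 had an unadjusted limma p under 0.05 and 13 were called. The main fit takes its spread from all groups fitted together, so its low count does not show that Reelin had no effect. Impad1 was 51.2 ± 0.3 CPM with Reelin and 16.5 ± 1.11 CPM with PBS (log2 fold change 1.58 ± 0.09, limma adjusted p = 3.18e-05). The PBS libraries were the exception, since the other 10 libraries of the table held 49.11 to 58.5 CPM. In the separate 4-library rat table Impad1 was also split, at 52.17 CPM in si-Control_t replicate 2 and 14.68 to 16.78 CPM in the others, so its call is uncertain. LOC108348173, the gene that fell, was at 6.13 and 6.02 CPM with PBS and listed at 0 in the other 14 rat libraries. Leaving out 1 library at a time gave 5 to 10 called genes. Of 36 lists 2 were called. Mitochondrially encoded transcripts fell (10 of 10 negative, median log2 fold change -0.42, camera adjusted p = 4.01e-05, and adjusted p = 0.977 with an estimated correlation), and so did nuclear genes of oxidative phosphorylation (32 of 38 negative, median -0.04, adjusted p = 5.98e-05, and adjusted p = 0.977 with an estimated correlation). Mt-nd1, a complex I subunit, was 1434 ± 770 against 1902 ± 29 CPM. Neither list was called without Reelin replicate 1 (adjusted p = 0.769 and 0.213, with medians of 0.06 and -0.04), and the median of the mitochondrially encoded list was -0.92 without Reelin replicate 2.

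The third comparison asked what more receptor did, using virus carrying Vldlr for 72 h. The treatment text names a GFP virus as its comparator. The Control libraries were assigned by elimination from 2 columns named Blank, which limits every statement about this comparison. Vldlr was 656.5 and 888.7 CPM in Vldlr OE replicates 1 and 2, and 576.6 and 379 CPM in Control columns 1 and 2. The size of its change thus depends on the Control library used. The means were 773 ± 164 and 478 ± 140 CPM (n = 2 each), a log2 fold change of 0.71 ± 0.18 with no overlap of replicates. It did not pass over all genes (limma adjusted p = 0.958) and passed when adjusted over the list alone (0.00959). The only call among 13860 genes was LOC100910669, listed at 0 in both Control libraries and at 12.95 and 11.84 CPM in Vldlr OE. It was also at 11.72 to 18.13 CPM in the PBS and Reelin libraries. At an unadjusted p under 0.05 there were 626 genes, with 693 expected by chance. Leaving out 1 library at a time gave 2 to 257 called genes, with 257 without Vldlr OE replicate 2 and 80 without Control column 1. Of 36 lists 11 were called. Mitosis genes fell as a group (38 of 39 negative, median log2 fold change -0.49, camera adjusted p = 1e-16, and adjusted p = 0.732 with an estimated correlation). DNA replication genes did too (37 of 38 negative, median -0.34, adjusted p = 7.47e-14, and adjusted p = 0.732 with an estimated correlation). Racgap1, a cytokinesis regulator, was 6.82 ± 0.998 against 14.2 ± 7.62 CPM, and the replication helicase subunit Mcm4 was 32 ± 3.27 against 45.6 ± 9.61 CPM. These changes rested on Control column 2: without it the medians were -0.06 and -0.09 and the adjusted p 0.316 and 0.0573. Without Control column 1 they were -0.99 and -0.60, and without Vldlr OE replicate 2 DNA replication had a median of -0.19.

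Cell cycle inhibitors and p53 targets rose in Vldlr OE (20 of 29 positive, median log2 fold change 0.08, camera adjusted p = 0.00195, and adjusted p = 0.732 with an estimated correlation), but not without Control column 2 (median 0.02, adjusted p = 0.214). The median was 0.17 without Control column 1 and 0.13 without Vldlr OE replicate 2. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was the only member that passed when adjusted over the list alone, at 425 ± 21.5 against 298 ± 55.6 CPM. Interferon-response genes rose (39 of 45 positive, median 0.27, adjusted p = 6.12e-13, and adjusted p = 0.732 with an estimated correlation), from low levels. Ifit3, the member that passed when adjusted over the list alone, was 3.24 ± 0.92 against 1.02 ± 0.07 CPM, and the median was 0.18 without Control column 2.

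**Figure D2:**
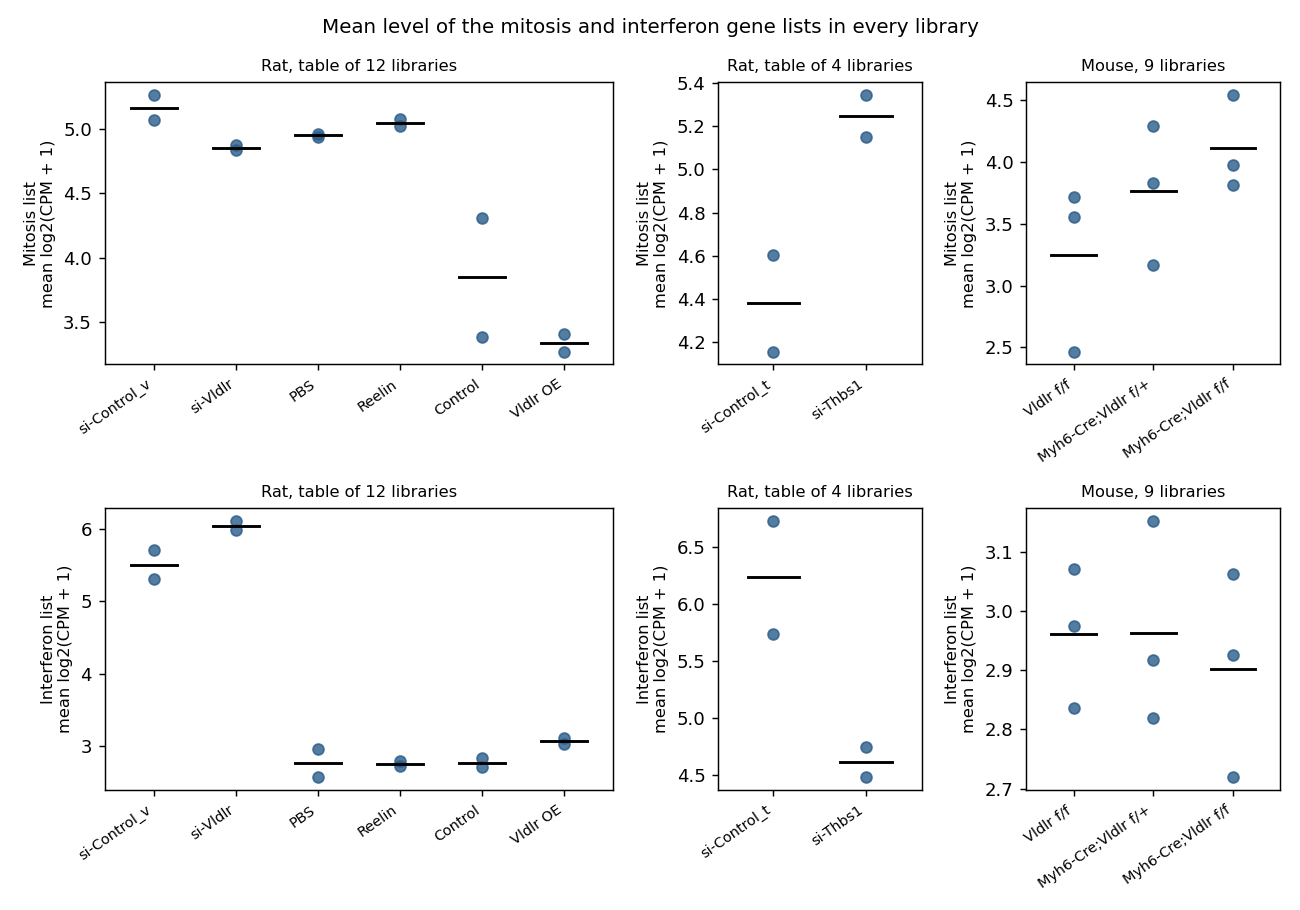
Mean log2(CPM + 1) over the members of the mitosis list (top) and the interferon list (bottom) in each library, by group, for the 3 tables, where libraries are points and group means are bars, and vertical axes differ between panels and do not start at 0. In the rat tables the siRNA libraries have interferon list means of 4.479 to 6.733 and the other libraries 2.568 to 3.109, and Control column 2 has the higher mitosis value of its group, 4.307 against 3.388.

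The fourth comparison asked what loss of Thbs1 did (siRNA, 50 nM, 60 h). Thbs1 was 744.6 and 545.9 CPM in si-Thbs1 replicates 1 and 2, and 943.5 and 892.1 CPM in those of its si-control. The size of the fall thus depends on the si-Thbs1 library used. The means were 645 ± 141 and 918 ± 36.3 CPM (n = 2 each), a log2 fold change of -0.52 ± 0.19 without overlap. The change did not pass limma's test (adjusted p = 0.821 over all genes and 0.103 adjusted over the list alone). Vldlr was 226 ± 84.1 against 210 ± 72.1 CPM. It was higher in replicate 1 than in replicate 2 of both groups (285 and 166 CPM in si-Thbs1, 261.3 and 159.4 CPM in its si-control). Of 13416 genes, 4 rose and 2 fell, and 741 had an unadjusted p under 0.05, with 671 expected by chance. Of these 6 genes, 5 were listed at 0 in a whole group, among them Ebna1bp2 (0 in both controls, 15.32 and 16.57 CPM in si-Thbs1) and Rbm12 (0 in both si-Thbs1 libraries, 13.52 and 15.99 CPM in the controls). The other 3 have predicted or clone identifiers: AABR07035375.1 (0 in both controls, 6.53 and 7.01 CPM in si-Thbs1), LOC100911917 (0 in both controls, 10.6 and 13.5 CPM in si-Thbs1) and LOC100910833 (0 in both si-Thbs1 libraries, 18.8 and 19.2 CPM in the controls). Ebna1bp2 and Rbm12 were also at 0 in some libraries and expressed in others of the larger rat table. The sixth, Rpl35al1, a name given to a ribosomal protein gene copy, was 57 ± 3.09 against 2.89 ± 0.89 CPM, and is uncertain because reads of near-identical copies can be split. Without the filter on low genes 0 genes were called, and 1014 had an unadjusted p under 0.05. With the replicate number as a block 43 genes were called, but 2 pairs are too few to take the numbers as pairing.

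Of 36 lists 9 were called for si-Thbs1. Among them were calcium and ion channels, sterol synthesis, epicardial and mesothelial markers and mitochondrially encoded transcripts. The last took 5.53% and 5.06% of CPM in the controls and 4.22% and 5.02% in si-Thbs1. Proliferation genes rose as groups. All 39 mitosis genes were higher with a median of 1.86-fold (camera adjusted p = 2.29e-44, and adjusted p = 0.548 with an estimated correlation). Over all genes 0 passed, and 37 passed when adjusted over the list alone. The median log2 fold change was 0.89, and 1.1 without si-Control_t replicate 1 and 0.67 without its replicate 2. Nusap1, a spindle protein, was 35.3 ± 0.798 against 18 ± 1.81 CPM and the kinesin Kif4a was 27.7 ± 1.43 against 13.5 ± 2.2 CPM. All 38 DNA replication genes were higher (median 1.48-fold, adjusted p = 1.49e-28, and adjusted p = 0.548 with an estimated correlation). Of them 25 passed when adjusted over the list alone and 0 over all genes, with Uhrf1 at 33.7 ± 0.01 against 18.2 ± 3.57 CPM.

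Interferon-response genes fell after si-Thbs1: all 44 were lower, with a median 2.97-fold lower (camera adjusted p = 3.4e-63, and adjusted p = 0.548 with an estimated correlation), and 43 passed when adjusted over the list alone. Over all genes 0 passed. The median log2 fold change was -1.57, and -2.07 without si-Control_t replicate 1 and -1.08 without its replicate 2. Cxcl10, an interferon-induced chemokine, was 12.2 ± 5.51 against 116 ± 78.3 CPM and Isg15, a ubiquitin-like antiviral protein, was 45 ± 16.4 against 252 ± 133 CPM. Genes of NF-kappaB inflammation fell (25 of 25 negative, median log2 fold change -0.42, adjusted p = 3.22e-15, and adjusted p = 0.548 with an estimated correlation), with the chemokine gene Ccl5 and the cytokine gene Tnf passing when adjusted over the list alone. The median of this list was -0.68 without si-Control_t replicate 1 and -0.35 without its replicate 2, and 0 of its genes passed over all genes. Markers of macrophages and leukocytes fell as well (16 of 19 negative, median -0.27, adjusted p = 2.67e-07, and adjusted p = 0.548 with an estimated correlation); Csf1r was 21.5 ± 0.942 against 29.7 ± 2.02 CPM. With 4 libraries the fit recovered 33.3% of genes changed 4-fold and 0% of those changed 2-fold in simulated data. A fit with 1 library left out holds 1 library in a group, and the spread then comes from the other group alone. Its count of called genes thus cannot be set against that of the full fit. Leaving out 1 library at a time gave 14 to 185 called genes, the highest without si-Control_t replicate 1.

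In mouse, Vldlr (chromosome 19, 27216484 to 27254231, plus strand, GRCm38, protein coding) was 78.5 ± 6.9 CPM in Myh6-Cre;Vldlr f/f, 103.5 ± 7.32 CPM in Myh6-Cre;Vldlr f/+ and 156 ± 43.7 CPM in Vldlr f/f (n = 3 each). The log2 fold change against Vldlr f/f was -0.94 ± 0.23 with both copies floxed, which did not pass over all genes (limma adjusted p = 0.997) and passed when adjusted over the list alone (0.00644). With a single floxed copy it was -0.55 ± 0.23 (adjusted p = 0.999 over all genes and 0.119 adjusted over the list alone). The values are of the whole gene, and which exons are floxed is not given in the sources used here. Reln (chromosome 5, 21884454 to 22344702, minus strand) was 5.13 ± 0.947 CPM in Myh6-Cre;Vldlr f/f and 6.66 ± 2.35 CPM in Vldlr f/f. Thbs1 (chromosome 2, 118111876 to 118127133, plus strand) was 60.5 ± 30.2 and 64.5 ± 29.4 CPM.

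No gene of 14922 was called by limma between Myh6-Cre;Vldlr f/f and Vldlr f/f. At an unadjusted p under 0.05 there were 453, with 746 expected by chance. On whole steps recovered from the CPM, edgeR called 0 and DESeq2 called 4, which all have clone or predicted identifiers and were lower (Gm47283, RP23-388P16.7, RP23-391M18.7 and RP24-64D24.6). Median-ratio scaling moved the median log2 fold change of all genes from -0.11 to 0.00. Of 40 lists 13 were called. Mitosis genes rose as a group (39 of 40 positive, median 1.85-fold, camera adjusted p = 4.59e-37, and adjusted p = 0.364 with an estimated correlation), with 0 passing when adjusted over the list alone. Ccna2, cyclin A2, was 43.8 ± 10.7 against 19.5 ± 8.33 CPM and Top2a was 56.6 ± 11.5 against 28.6 ± 14.3 CPM. Without Vldlr f/f replicate 1, whose Mki67 was 11.72 CPM against 60.53 and 85.71 CPM in the other libraries of its group, the median log2 fold change was 0.52 in place of 0.89. With median-ratio scaling it was 1.01. Fatty acid oxidation genes fell (36 of 39 negative, median -0.44, adjusted p = 4.79e-07, and adjusted p = 0.5 with an estimated correlation), with Slc27a1, a fatty acid transporter, at 120.0 ± 33 against 241 ± 80 CPM. With median-ratio scaling the median was -0.31.

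Markers of other cell types moved with this genotype. Epicardial and mesothelial markers were higher (15 of 16 positive, median log2 fold change 0.73, camera adjusted p = 1.75e-09, and adjusted p = 0.364 with an estimated correlation), with the keratin gene Krt18 at 18.6 ± 4.48 against 9.05 ± 2.57 CPM. The median was 0.38 without Myh6-Cre;Vldlr f/f replicate 3 and 0.46 without Vldlr f/f replicate 3, and 0.84 with median-ratio scaling. Smooth muscle and pericyte markers were lower (15 of 18 negative, median -0.27, adjusted p = 0.00798, and adjusted p = 0.364 with an estimated correlation). Abcc9, a potassium channel subunit also expressed in cardiomyocytes, was the member that passed when adjusted over the list alone, at 135 ± 38 against 292 ± 75.6 CPM. That list was not called without Myh6-Cre;Vldlr f/f replicate 3 (adjusted p = 0.363) or without Vldlr f/f replicate 2 (adjusted p = 0.0538). Its median was -0.16 without Vldlr f/f replicate 3 and -0.16 with median-ratio scaling. Mitochondrially encoded transcripts took 19.5%, 23.8% and 15.4% of CPM in Myh6-Cre;Vldlr f/f replicates 1, 2 and 3 and 13.7%, 19.3% and 15.2% in those of Vldlr f/f. Their list was called higher (11 of 12 positive, median 0.19, adjusted p = 0.000985, and adjusted p = 0.621 with an estimated correlation), but not without Myh6-Cre;Vldlr f/f replicate 2 (adjusted p = 0.246) or without Vldlr f/f replicate 1 (adjusted p = 0.0588), where the medians were 0.07 and 0.11. Its median was 0.36 without Myh6-Cre;Vldlr f/f replicate 3, 0.33 without Vldlr f/f replicate 2 and 0.32 with median-ratio scaling. The female transcript Xist and the Y-linked Ddx3y placed 3 of 3 Myh6-Cre;Vldlr f/+ libraries, 2 of 3 Myh6-Cre;Vldlr f/f libraries and 1 of 3 Vldlr f/f libraries as female, so the genotypes also differ in sex.

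For Myh6-Cre;Vldlr f/+ against Vldlr f/f limma and edgeR on the recovered steps called 0 genes (362 at an unadjusted p under 0.05 in limma), and DESeq2 called 6, of which Kdm5d is Y-linked. Of 40 lists 13 were called. Epicardial and mesothelial markers were higher (16 of 16 positive, median 2.11-fold, camera adjusted p = 8.22e-13, and adjusted p = 0.464 with an estimated correlation), with Msln, mesothelin, at 113 ± 77.6 against 39.3 ± 15.8 CPM. Atrial genes were higher (11 of 12 positive, median 1.82-fold, adjusted p = 3.79e-09, and adjusted p = 0.462 with an estimated correlation), with the atrial light chain gene Myl7 at 1262 ± 725 against 422 ± 224 CPM. Mitosis genes rose (40 of 40 positive, median 1.44-fold, adjusted p = 6.46e-13, and adjusted p = 0.523 with an estimated correlation) and fatty acid oxidation genes fell (37 of 39 negative, median -0.52, adjusted p = 4.76e-10, and adjusted p = 0.464 with an estimated correlation). No member of these 4 lists passed when adjusted over the list alone. The mitosis median log2 fold change was 0.53, and 0.15 without Vldlr f/f replicate 1, 0.21 without Myh6-Cre;Vldlr f/+ replicate 3 and 0.83 without its replicate 1. Without Myh6-Cre;Vldlr f/+ replicate 1 the epicardial median was 0.60 in place of 1.08 and that of fatty acid oxidation -0.32. The fatty acid oxidation median was -0.31, -0.81 and -0.34 without Vldlr f/f replicates 1, 2 and 3, and the atrial median was 0.56 in place of 0.86 without Vldlr f/f replicate 3. With sex as a covariate, chosen after seeing the data, the atrial median was 0.26 and the mitosis median 0.83.

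Between the Cre genotypes, limma and edgeR on the recovered steps called 0 genes (138 at an unadjusted p under 0.05 in limma) and DESeq2 called 9. With the pairs of equal number as a block limma also called 0 genes, with 369 at an unadjusted p under 0.05. Of 40 lists 4 were called, and 6 with the block. In simulated data for this comparison a list of unchanged genes had an unadjusted camera p of 0.00607. Atrial genes were lower in Myh6-Cre;Vldlr f/f than in Myh6-Cre;Vldlr f/+ (12 of 12 negative, median log2 fold change -0.83, camera adjusted p = 1.99e-08, and adjusted p = 0.976 with an estimated correlation), and mitosis genes were higher (39 of 40 positive, median 1.29-fold, adjusted p = 3.39e-11, and adjusted p = 0.976 with an estimated correlation). The mitosis median log2 fold change was 0.37, and 0.08 without Myh6-Cre;Vldlr f/+ replicate 1, 0.62 without its replicate 3 and 0.18 without Myh6-Cre;Vldlr f/f replicate 3. With sex as a covariate it was 0.24 (adjusted p = 0.00215). The atrial median was -0.55 without Myh6-Cre;Vldlr f/+ replicate 1. Vldlr differed by -0.40 ± 0.23 on the log2 scale (limma adjusted p = 1 over all genes, 0.999 with the block, and 0.344 adjusted over the list alone). The groups did not overlap: Vldlr was 71.33, 78.89 and 85.11 CPM in Myh6-Cre;Vldlr f/f and 98.43, 111.9 and 100.2 CPM in Myh6-Cre;Vldlr f/+. Any pairing would thus show it lower in all 3 pairs, so its pairs add no evidence. Top2a and Nusap1 were higher in all 3 pairs of equal number, but a pairing is not shown. Neither passed with the block (limma adjusted p = 0.999 each).

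The responses to the receptor and ligand treatments were compared directly in the 12-library rat fit. The Vldlr response differed by -1.23 ± 0.26 on the log2 scale between si-Vldlr and Vldlr OE (limma adjusted p = 0.706 over all genes and 0.00237 adjusted over the list alone). Across 13860 genes, the log2 fold changes of si-Vldlr and Vldlr OE, which change the receptor in opposite directions, had a Pearson correlation of 0.248 and a Spearman correlation of 0.284. Genes are not independent replicates. LOC100910669 was the 1 gene called in both. Against the shared Vldlr f/f libraries, the mouse genotypes had a correlation of 0.623 across genes, where unchanged groups simulated against shared controls gave 0.502. The covariance was 0.0762 and the simulated one 0.0806, so it was not above that of shared controls alone. The simulated libraries were independent. The simulation thus leaves out any pairing of the Cre genotypes by number, which would raise the values of unchanged groups. The 3 controls were too few to be split with at least 2 on each side.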

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

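All tests of explanations in this part were chosen after the results were seen; the differences between responses were planned. The difference between the si-Vldlr and Vldlr OE responses was called for 1 gene, Nefm (2.14 on the log2 scale). Nefm was not called without Control column 1 (adjusted p = 0.0517), Control column 2 (0.0849), Vldlr OE replicate 1 (0.125), Vldlr OE replicate 2 (0.074) or si-Vldlr replicate 2 (0.0741), nor without the filter on low genes. Its difference was 1.90 to 2.39 over the left-out libraries. Between Reelin and Vldlr OE it was called for 3 genes: Impad1 (1.66), LOC100910669 (-3.77) and LOC108348173 (-2.82). Between Reelin and si-Vldlr it was called for 2 genes, Impad1 (1.47) and LOC108348173 (-2.82).

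Several calls rest on genes listed at 0 in whole libraries. Of the genes tested in 12 rat libraries, 114 were at exactly 0 in some library and at 5 CPM or more in another, and 94 of them (82.5%) also switched between the 2 replicates of a group. Mapk7, a kinase gene, was at 0 and 53.84 CPM in the PBS replicates. This is consistent with reads being given to another overlapping or near-identical gene, and no biological explanation was tested. Of the 114, the other 20 did not switch within a group, among them the called genes Abhd10, LOC100910669 and LOC108348173. The share of 82.5% thus does not cover these calls. Without genes that switch, the calls were 2 for si-Vldlr, 1 for Reelin, 0 for Vldlr OE and 1 for si-Thbs1.

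Interferon genes rose with si-Vldlr and fell with si-Thbs1. Leukocyte content was not settled as a cause. In si-Vldlr leukocyte markers had a median of -0.10 beside 0.55 for interferon genes, so a higher leukocyte content was not seen there. In si-Thbs1 both fell, with medians of -0.27 and -1.57, a ratio of 0.172. Interferon genes need not move in proportion to leukocyte markers, so the ratio cannot decide. Removal of such cells by the pre-plating step was not measured. Adgre1 and Csf1r, of the macrophage and leukocyte list, were still 50.8 and 21.5 CPM in si-Thbs1 and 86.0 and 29.7 CPM in its si-control. Transfection may contribute, since Isg15 was at least 33.5 CPM in the 8 transfected rat libraries and at most 8.26 CPM in the other 8. Differences in transfection between libraries cannot be told apart from the siRNA targets, because each target has its own libraries; the knockdown itself stays open.

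Mitosis genes were higher in Myh6-Cre;Vldlr f/f (median log2 fold change 0.89) and lower in Vldlr OE (-0.49), but they were also lower in si-Vldlr (-0.33). The directions with Cre and floxed Vldlr in mouse and with siRNA in rat were thus opposite, a difference that was not tested. Vldlr f/f has no Cre and no group has Cre alone, so in comparisons with Vldlr f/f an effect of Cre cannot be told apart from loss of Vldlr. A single Control library could account for the value in Vldlr OE: without Control column 2 the median was -0.06 (-0.0551). In mouse, the median without Vldlr f/f replicate 1 was 0.522, so part of the value rested on that library and part remained without it. A lower share of cardiomyocytes was not settled. Epicardial and smooth muscle markers, the highest and lowest of the cell type lists compared, differed by 1.00 on the log2 scale. Fibroblast, endothelial and macrophage markers lay closer together, with medians of 0.09, -0.13 and 0.12. The 2 standard errors of that difference (0.278) were taken over genes of the same libraries, which are not independent, so they cannot decide it. With sex as a covariate the median was 1.07 in place of 0.89, so adjusting for sex did not lower it. The list was still called at the preset correlation, but that decides nothing about sex. The same test called 3 to 14 lists in other splits of the compared libraries. The share of cardiomyocytes, a change in epicardial cells, Cre and the genotype stay open.

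The 6 libraries of each mouse comparison can be split in 10 ways, too few for a share under 0.05. The real splits called 0 genes each, with at most 6 (Myh6-Cre;Vldlr f/f against Vldlr f/f), 40 (Myh6-Cre;Vldlr f/+ against Vldlr f/f) and 4 (between the Cre genotypes) in another split. A count of 0 is reached by each of the 10 splits whatever the data, so the gene counts test nothing about the grouping. The 40 genes came from a split that mixed genotypes, which points to a structure of the samples. Lists called were 13 against a highest other of 14, 13 against 14, and 4 against 18, and 2, 2 and 10 of the 10 splits called as many as the real one. Between the Cre genotypes equal numbers were taken as pairs, which is not shown. There the other 3 splits that part all 3 pairs called 0 to 1 genes and 8 to 9 lists, and the rest keep a pair together.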

How the results depend on the processing

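Median-ratio scaling left the counts of called genes within 1.5 times, differences of responses included, and so did a pseudocount of 0.1 for the 7 comparisons it was run on. Library size only repeats the fit as reported and tests nothing. Without a filter the counts were 4 for Vldlr OE, 0 for si-Thbs1 and 0 for the difference of si-Vldlr and Vldlr OE. With the compared groups alone they were 8 for si-Vldlr, 13 for Reelin, 8 for Vldlr OE and 1 for Myh6-Cre;Vldlr f/f against Vldlr f/f. DESeq2 called 4 (Myh6-Cre;Vldlr f/f against Vldlr f/f), 6 (Myh6-Cre;Vldlr f/+ against Vldlr f/f) and 9 (between the Cre genotypes), and it made 37 false calls in simulated data, which were made for the first of these only. Without switching genes, chosen after seeing the data, counts were 2 for si-Vldlr, 1 for Reelin, 0 for Vldlr OE and 1 for si-Thbs1. The other alternatives added after seeing the data (edgeR on the steps, sex and a residual component as covariates) kept mouse counts of called genes at 0. The cause of these changes was not tested. DESeq2 and edgeR were not run on rat.

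With the replicate block si-Thbs1 gave 43 called genes and 17 called lists in place of 6 and 9, and 8 of the 39 mitosis genes passed over all genes in place of 0. Its pairs correlated at 0.409, but 2 pairs are too few to take the numbers as pairing. The block moved no other count of genes or lists by over 1.5 times and ended no other described call. No paired analysis of Vldlr OE against Control was made, because the columns named Blank were matched to the group only and their numbers were not tied to the labels' replicate numbers. With an estimated correlation 0 lists were called in each of the 7 comparisons.

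Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 4 to 167 genes for si-Vldlr, 5 to 10 for Reelin, 2 to 257 for Vldlr OE (257 without Vldlr OE replicate 2, 80 without Control column 1), 14 to 185 for si-Thbs1, 0 to 1 for each Cre genotype against Vldlr f/f, and 0 between them. The differences of responses gave 0 to 6 (si-Vldlr and Vldlr OE), 3 to 67 (Reelin and Vldlr OE, 67 without Vldlr OE replicate 2 and 30 without Control column 1) and 5 to 9 (Reelin and si-Vldlr). Lists called were 11 to 23 for si-Vldlr, 0 to 4 for Reelin, 9 to 13 for Vldlr OE, 16 to 18 for si-Thbs1, 11 to 15 for Myh6-Cre;Vldlr f/f and 7 to 15 for Myh6-Cre;Vldlr f/+ against Vldlr f/f, and 3 to 16 between them. Sterol synthesis in si-Thbs1 reversed without si-Thbs1 replicate 1 (adjusted p = 0.0435), and its adjusted p ranged from 2.28e-17 to 0.722 over the left-out libraries. Fragment depth is unknown, so it sets no limit that can be given.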

Other observations

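The rat control groups differed in their own levels. Mki67, a proliferation marker, was 36.8 ± 21.2 CPM in Control, 80.5 ± 3 CPM in PBS and 95.1 ± 4.46 CPM in the si-control of si-Vldlr, and 19.6 ± 2.81 CPM in Vldlr OE (n = 2 each). Cdkn1a was 298 ± 55.6, 119 ± 2.19 and 119 ± 12.4 CPM in these controls and 425 ± 21.5 CPM in Vldlr OE. Vldlr itself was 478 ± 140, 359 ± 15.8 and 255 ± 3.3 CPM in the 3 control groups. The Control libraries were assigned by elimination. These groups were treated for different times and were not compared by a test.

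Mitochondrially encoded transcripts took 13.7% to 23.8% of CPM in the mouse libraries and 2.14% to 6.26% in the 12-library rat table. In that rat table the lowest share was in Reelin replicate 1 and the highest in si-Control_v replicate 2. In mouse the shares were 20.7%, 17.3% and 16.2% in Myh6-Cre;Vldlr f/+ replicates 1, 2 and 3.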
